A study of Mus musculus with 14 samples.

How the data were processed

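RNA was measured in mouse peritoneal macrophages that had been sorted for both CD11b and F4/80. There were 14 arrays in 4 groups, 1 array per sample: 3 from mice given the PBS vehicle (PBS), 4 from mice given IL-4 complex (IL-4c), 3 from mice given thioglycollate medium (Thio) and 4 from mice given both (Thio+IL-4c). Per the labels' protocols, IL-4 complex was 5 µg of IL-4 with 25 µg of the anti-IL-4 antibody 11B11, and thioglycollate was 2 ml of a 4% medium, all injected into the peritoneum. Binding to the antibody prolongs the activity of IL-4 in the animal. Groups were taken from the treatment label of each sample and replicate numbers from the sample titles.

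The authors deposited 1 scanner table per array, whose values are spot intensities on a linear scale from a single dye (Cy3), together with a table of their own processed log2 values for the same arrays. Per the file headers, the intensities were extracted with Agilent Feature Extraction 11.0.1.1, while the submitters' processing notes give version 11.5 of that software and limma. The processed signal used here is, per the file headers, an intensity that the software had background-subtracted and detrended within the array. The authors' deposited log2 table has a median of 9.2341 on every array. It correlates across probes with the log2 median signal of the same array at r of 0.9882 to 0.9943, so its direction is settled by the scanner values. The correlation is the same for any log base and cannot settle that. The background correction behind it is not given in the sources used here.

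Each array held 62976 spots, of which 3671 were control spots that were left out. The remaining spots were of 55681 probes. The files carry no gene symbols, so probes were named through their accession, without its version, in a RefSeq gene table of the mouse assembly GRCm38.p6. That gave 1 symbol to 27235 probes, covering 20660 symbols, and left 28446 probes unnamed. No spot was saturated. Between 113 and 165 spots per array carried an outlier mark of the scanner software and were left out.

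The values used are log2 of the processed signal minus the 75th percentile of that signal on the same array. Spots of 1 probe were averaged. A probe was kept if it was well above background on at least 3 arrays, and a gene was represented by its brightest probe over the 14 arrays, which gave 20343 genes. Where the other probes of a named gene went the opposite way, this is said beside it. A level is therefore relative to the 75th percentile of its array, and levels of different probes cannot be set against each other.

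Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), with 1 mean per group and all 14 arrays in a single fit, so that groups of 3 and 4 shared an estimate of the spread. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all genes tested in that comparison. The 5 comparisons were IL-4c versus PBS, Thio versus PBS, Thio+IL-4c versus Thio, Thio+IL-4c versus IL-4c, and the interaction, which is the IL-4c effect in elicited cells minus the IL-4c effect in resident cells. Fold changes are given as log2 values with the standard error (SE) of the fit, and group levels as the mean ± SD of the arrays. All p-values beside genes are limma's adjusted values.

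A gene whose probes were all below the scanner's threshold for well above background on every array of a group has only a bound there. For such genes the bright group's mean was set against the mean, over the dim group's arrays, of the higher of 2 values: the lowest signal among probes well above background on that array and the dim probe's own signal. The result is written as at least N-fold. Well above background was counted over all probes of a gene. Among named genes with several probes this differed from the probe used only for Pdpn.

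There were 26 gene lists, fixed before the data were examined: programs of macrophages, markers of other cell types that the sort could let through, and a list of stress genes. Each list was tested per comparison with camera at a preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the lists, and its called members were counted over all genes and adjusted over the list alone. Named genes came from a rule. It took, per comparison, the 5 largest rises and the 5 largest falls among called genes whose arrays did not overlap (for the interaction, without that demand), leaving out clone and predicted names. It also took up to 2 called members with the largest rise and 2 with the largest fall from each list, and 14 index genes whatever their call. A demand that the 10 largest changes be well above background on both sides was added after the data were seen. The rule returned 491 pairs of gene and comparison, of which 268 were taken for the text after their values were visible, so the list members named are a selection. The comparisons, tests, naming rule and the alternative settings other than those named as added were fixed before the data were examined.

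The arrays were on 2 slides, each scanned once. Slide 1 held the PBS and IL-4c arrays and Thio 1, and slide 2 held Thio 2 and 3 and all Thio+IL-4c arrays. IL-4c versus PBS therefore lies within slide 1. With slide as a block, Thio versus PBS rests on Thio 1, Thio+IL-4c versus Thio rests on Thio 2 and 3, and Thio+IL-4c versus IL-4c is linked only through the Thio arrays of both slides. The interaction with slide as a block lies within slides. Values from that fit are given for part of the genes and lists of the comparisons that cross the slides. For genes whose spot on Thio 1, or on both other Thio arrays, was left out no such value exists, so that 20324 genes were tested there.

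The number of arrays limits the precision. The method was tested on simulated data: values for 20159 genes were drawn with the spread of the real arrays and 200 genes were changed. Of genes changed 2-fold, 47% were called for IL-4c versus PBS, 34% for Thio versus PBS, 52% for Thio+IL-4c versus Thio, 44% for Thio+IL-4c versus IL-4c and 26% for the interaction. Of genes changed 4-fold the shares were 64%, 58%, 72%, 66% and 43% in the same order. Between 1 and 7 unchanged genes were called per comparison. The simulated values held no difference between the slides on which the arrays lay. These shares and counts therefore do not carry over to the comparisons that cross the slides, which are all but IL-4c versus PBS. How many genes are called there because of slide was not tested by the simulation. For IL-4c versus PBS the shares do not carry over directly either. The Benjamini-Hochberg cutoff depends on how many genes change. The simulation changed 200 of 20159 genes, while 6546 of 20343 were called in the real IL-4c versus PBS comparison. The simulated shares are therefore not the sensitivity of that comparison.

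The alternatives were quantile normalization, normexp background correction of the median signal (offset 50; the mean signal that had been planned is not among the columns) with quantile normalization, the authors' log2 table, 2 other filters on dim probes, the mean of a gene's probes (without a value on an array where a spot of any of them was left out), only the groups compared in the fit, trended and robust variance priors, array weights, outlier spots kept, the replicate number as a block, slide as a block, a stricter threshold, and each array left out in turn. Slide as a random block and leaving out genes below background in both groups were added after the data were seen. No 2 arrays held identical values, and the highest correlation between 2 arrays was 0.987.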

Results

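The series set macrophages already present in the mouse peritoneum against macrophages recruited there by thioglycollate, an irritant broth that draws blood monocytes into the cavity, and asked how each kind takes on the alternatively activated state that IL-4 induces. Resident cells came from mice given PBS (3 arrays) or IL-4c (4 arrays) and elicited cells from mice given thioglycollate alone (3 arrays) or with IL-4c (4 arrays). Every sample was sorted as CD11b and F4/80 positive before RNA was extracted. The 75th percentile of the processed signal ran from 1275 to 3883 between arrays, and between 79.2% and 95.7% of probes were well above background. It was 1275.4 to 1818.5 on the PBS arrays and 3058.7 to 3883.4 on the IL-4c arrays. Probes well above background made up 79.2% to 84.8% and 86.1% to 92.6% there. Array brightness and treatment therefore coincide in IL-4c versus PBS. The labels do not settle whether the replicates of a group came from separate animals, so p-values measure only the spread between these samples.

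Over 20159 genes, thioglycollate took 51.5% of the sum of squares between arrays, IL-4c 13.4%, their interaction 9.37% and the spread within groups 25.8%. Thioglycollate nearly coincides with slide, so most of its share cannot be told apart from slide. The first principal component held 62.2% of the variance and the second 12.9%. The share of thioglycollate fell to 7.40% when slide was entered first, since the elicited arrays other than Thio 1 were all on slide 2. Thio 1 correlated with Thio 2 and Thio 3 at r of 0.848 and 0.865 across genes, while Thio 2 and Thio 3 correlated at 0.984. Its correlations with the PBS arrays of its own slide were 0.917 to 0.931. Arrays of the other groups correlated within their group at 0.956 to 0.987.

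**Figure D1:**
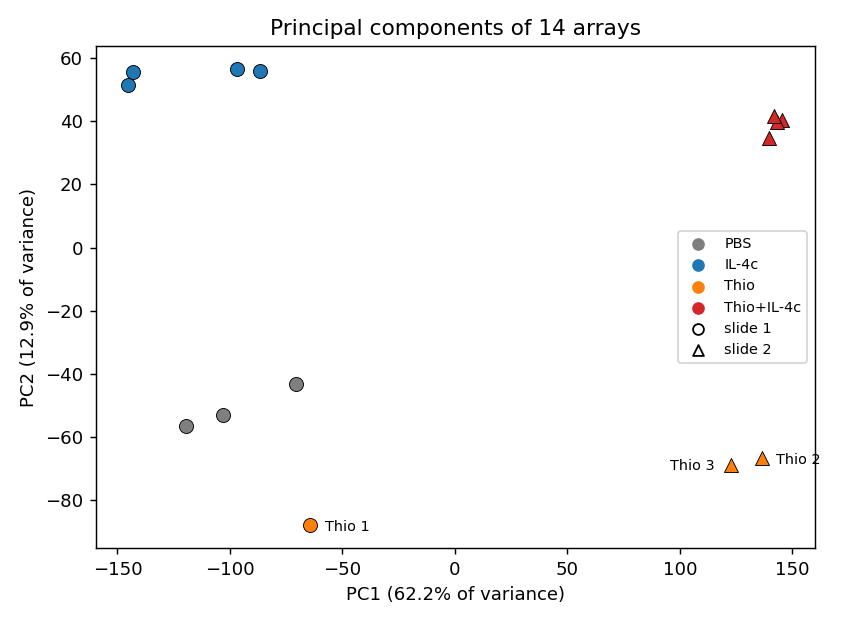
First and second principal components of the 14 arrays, with the share of variance of each on the axes; colour gives the group and shape the slide. IL-4c arrays lie above PBS arrays and Thio+IL-4c arrays above Thio arrays on the second component, and Thio 1, on slide 1, lies near the PBS arrays on the first component at -64.3, while Thio 2 and Thio 3 lie at 136 and 123.

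The first comparison asked what IL-4c does to resident macrophages. Arg1, which encodes the arginase that marks alternative activation, rose from 3.35 ± 0.43 in PBS (SD, n = 3) to 7.41 ± 0.13 in IL-4c (n = 4), a 16.7-fold difference. Chil3 (Ym1), a secreted chitinase-like protein, rose by 6.03 (SE 0.17) and its relative Chil4 by 9.73 (SE 0.21). Retnla, which encodes RELMα, was already high in PBS at 6.91 ± 0.10 and rose by 0.55 (SE 0.10, adjusted p = 0.0014). Mki67, a marker of proliferating cells, rose by 3.54 (SE 0.24), while the chemokine gene Cxcl13 fell by 9.41 (SE 0.32).

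After Chil4, the largest rises in resident cells were those of Timd2, a ferritin receptor (9.69, SE 1.25), Tmigd1 (9.30, SE 1.06), the water and glycerol channel Aqp3 (9.06, SE 0.31) and Mall (8.71, SE 0.49). Timd2, Tmigd1 and Mall were well above background on 1 of the 3 PBS arrays each, so the size of their rise rests on levels near the floor. After Cxcl13, the largest falls were those of the transglutaminase subunit gene F13a1 (-7.77, SE 0.27, and -4.18 on its other probe), the lysozyme gene Lyz2 (-7.28, SE 0.23), the lipoprotein lipase gene Lpl (-6.92, SE 0.23) and the chemokine gene Ccl3 (-6.92, SE 0.44). Ccl3 was well above background on 2 of the 4 IL-4c arrays. Ucp1, known as the mitochondrial uncoupling protein of brown fat, rose by 6.00 (SE 0.50) from -0.64 ± 0.54 to 5.35 ± 0.25. Aldh1a2, which makes retinoic acid, rose by 0.69 (SE 0.11), and the monocyte chemokine receptor gene Ccr2 fell by 3.66 (SE 0.26). The mannose receptor gene Mrc1 fell by 0.96 (SE 0.16) and the phosphatidylserine receptor gene Timd4 fell by 1.53 (SE 0.39). Pdcd1lg2 (PD-L2) differed by 0.47 (SE 0.20, adjusted p = 0.11; 0.49 and 0.04 with array weights) and Gata6, the transcription factor of resident peritoneal macrophages, by 0.05 (0.95). Cx3cr1 differed by -0.31 (0.28), but passed the threshold with slide as a block (0.044) and on the mean of its probes (-0.94, 0.0013), its other probe being at -1.56. Of the sort markers, Itgam (CD11b) differed by -0.17 (adjusted p = 0.29), with 1 of its 3 probes going the other way, and Adgre1 (F4/80) by -0.27 (adjusted p = 0.038), a sign that turned under quantile normalization (0.01), normexp with quantile normalization (0.03) and the authors' table (0.09). Pdcd1lg2, Aldh1a2, Ucp1, Cx3cr1 and Ccr2, as well as the retinoid list, are known to have been followed up by the study on these samples, so their results are not independent evidence.

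**Figure D2:**
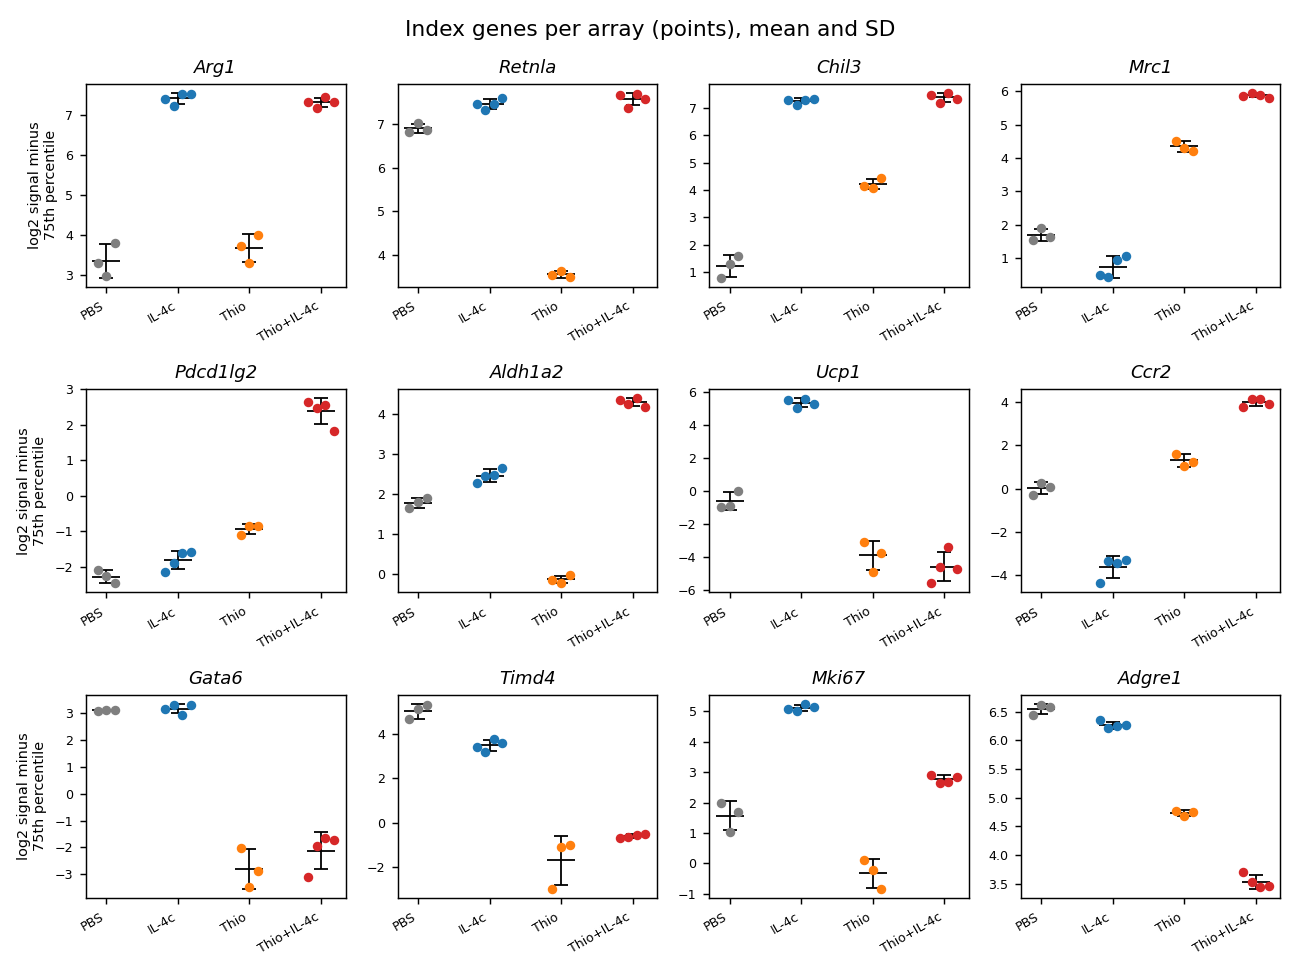
Levels of 12 index genes in each array (points) with the group mean and SD (bars), as log2 signal minus the 75th percentile of the array. Arg1, Retnla and Chil3 reach about the same level in both IL-4c groups, which lay on different slides. Ucp1 is high in IL-4c alone at 5.35, and Mrc1, Pdcd1lg2, Aldh1a2 and Ccr2 are highest in Thio+IL-4c.

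Proliferation genes rose together in resident cells given IL-4c. Of 34 measured cell cycle genes 33 rose and none fell, both over all genes and adjusted over the list alone, with a median of 3.11 (camera adjusted p = 3.6e-23). The ribonucleotide reductase gene Rrm2 rose by 4.83 and the mitotic checkpoint kinase gene Bub1 by 4.24. Genes of oxidative phosphorylation rose in 23 of 24 cases (24 adjusted over the list alone), with a median of 0.84 (3.2e-13), among them the cytochrome genes Cyc1 (1.83) and Cycs (1.63). For Cycs, 1 of 3 probes went the other way, and the mean of its probes did not pass the threshold (0.44, adjusted p = 0.43). Of 23 fatty acid oxidation genes 16 rose and 1 fell (17 and 1 adjusted over the list alone; camera 4.9e-07), led by the mitochondrial coactivator gene Ppargc1b (3.05) and the electron transfer flavoprotein gene Etfa (1.62). Of 24 cholesterol synthesis genes 17 rose (19 adjusted over the list alone) and none fell (7.3e-07), with the squalene epoxidase gene Sqle at 2.34 and Fdps at 2.28. Of 18 glycolysis genes 11 rose and 1 fell, the same numbers adjusted over the list alone (3.7e-05), and the glucose transporter gene Slc2a1 rose by 2.58. The adjusted p-values of these 5 lists with an estimated correlation between members were 0.054, 0.11, 0.15, 0.18 and 0.26 in the same order.

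Receptors and chemokines of resident macrophages mostly fell with IL-4c. Of 22 scavenger and phagocytic receptor genes 16 fell and 3 rose (16 and 4 adjusted over the list alone; median -1.55, camera adjusted p = 4e-06). The Fc receptor gene Fcgr1 fell by 6.70, being well above background on 3 of 4 IL-4c arrays, the scavenger receptor gene Marco by 3.91 and Cd36 by 3.13. Of 24 chemokine genes 15 fell and 1 rose on either count (1.7e-05). Of 16 complement genes 9 fell and 1 rose on either count (0.0045), the rise being that of C3 (1.74). Of 24 inflammatory genes 12 fell (13 adjusted over the list alone) and 1 rose (0.00092), with the pattern receptor gene Tlr2 at -3.63. The single rise was that of the cytokine gene Il6, by 3.81 (SE 0.26). Of 19 genes of the resident peritoneal macrophage list 11 fell (12 adjusted over the list alone) and 1 rose (3.7e-05), including the apolipoprotein gene Apoc1 (-5.40). With an estimated correlation the adjusted p-values of these 5 lists were 0.054, 0.11, 0.10, 0.15 and 0.054. Of 27 alternative activation genes 16 rose and 7 fell (18 and 7 adjusted over the list alone; 0.00092), and with an estimated correlation the adjusted p was 0.054. The cell adhesion gene Cdh1 (E-cadherin), a member of that list, was not well above background on any PBS array and was at least 16.2-fold higher in IL-4c.

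Antigen presentation genes of MHC class II fell in 6 of 13 cases and rose in 1 (9 and 2 adjusted over the list alone; camera adjusted p = 0.047), among them H2-Oa (-2.41, SE 0.46). That adjusted p was 0.41 with an estimated correlation, and with slide as a block it was 0.058. B cell markers, whose carriers express class II genes, moved with this group: 6 of 13 fell and none rose (7 and 0 adjusted over the list alone; median -1.20, 0.00092, and 0.11 with an estimated correlation), with Ms4a1 (CD20) at -3.72 and Cd79b at -3.50. T and NK cell markers fell in 4 of 15 cases on either count, none rising (0.045, 0.15 with an estimated correlation, 0.066 in the authors' table), with Cd2 at -2.18. In the list of immediate early and heat shock genes, a sign of handling, 5 of 14 fell and 2 rose (8 and 2 adjusted over the list alone; 0.034, and 0.41 with an estimated correlation). With slide as a block its adjusted p was 0.067. Its leading member, the heat shock gene Hspa1a, fell by 4.96 and varied among the PBS arrays with an SD of 1.30. Of 24 retinoid genes 3 rose and 3 fell on either count (0.73).

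In all, 6546 genes were called between IL-4c and PBS, 3431 higher and 3115 lower, of which 2702 differed at least 2-fold. Both groups lay on slide 1, so a block for slide cannot change these fold changes, only the estimated spread (8792 called).

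The second comparison set elicited against resident macrophages without IL-4c. Genes that mark resident peritoneal macrophages were far lower in Thio: Gata6 differed by -5.94 (SE 0.39), Timd4 by -6.72 (SE 0.41) and Cxcl13 by -10.13 (SE 0.34), with n = 3 arrays in each group. The collagen-degrading lysosomal protease gene Ctsk rose by 10.43 (SE 0.35). Podoplanin, Pdpn, had the largest rise by the naming rule, but its brightest probe was not well above background on any PBS array, and its other probe differed by 2.54. Of 19 measured genes of the resident list 18 fell and 1 rose, with a median of -5.94.

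The other large rises in elicited cells were those of Lhfpl2 (9.92, SE 0.64), the interleukin-7 receptor gene Il7r (9.09, SE 0.45) and the glycoprotein gene Gpnmb (8.99, SE 0.76), the last from Thio 2 and 3 only. The other large falls were those of the lipoxygenase gene Alox15 (-10.08, SE 0.70), the TGF-beta binding protein gene Ltbp1 (-9.47, SE 0.28), Serpinb10 (-8.95, SE 0.35) and the ectonucleotidase gene Nt5e (-8.84, SE 0.65), the last well above background on 2 of 3 Thio arrays. Retnla fell by 3.36 (SE 0.11), while Chil3 rose by 2.99 (SE 0.19) and Mrc1 by 2.65 (SE 0.18). Arg1 differed by 0.31 (SE 0.21, adjusted p = 0.25). Pdcd1lg2 rose by 1.34, Ccr2 by 1.28 and Cx3cr1 by 0.69 (adjusted p = 0.02; 0.075 without PBS 2; 2.35 on its other probe), whereas Aldh1a2 fell by 1.91 and Ucp1 by 3.28. Mki67 fell by 1.90, Adgre1 by 1.81 and Itgam by 1.81.

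The decline of the resident list (camera adjusted p = 1.2e-13) stayed past the threshold with an estimated correlation (0.0016), was the same in number adjusted over the list alone, and included the lubricin gene Prg4 (-8.45, and -4.41 on its other probe) and the matrix protein gene Thbs1 (-3.56). Of its members 18 fell and 1 rose with slide as a block. Of 26 lysosome genes 17 rose and 3 fell (17 and 4 adjusted over the list alone; 2.9e-06), and 21 rose and 1 fell with slide as a block. The vacuolar ATPase subunit gene Atp6v0d2 was not well above background on any PBS array and was at least 2050-fold higher in Thio. Of 27 genes of extracellular matrix and repair 15 rose and 6 fell (17 and 6 adjusted over the list alone; 0.00073), and 13 rose and 5 fell with slide as a block. Markers of mesothelial and stromal cells, which make matrix genes, rose in 5 of 12 cases, none falling (5 and 1 adjusted over the list alone; median 0.71, 0.19, and 0.55 with an estimated correlation; 3 and 1 with slide as a block). The metalloproteinase gene Mmp8, not well above background in PBS, was at least 65.6-fold higher, Mmp12 rose by 6.31 and Tgfbi fell by 3.35. Of 24 cholesterol synthesis genes 14 rose and none fell (16 and 1 adjusted over the list alone; 0.00073; 12 and 0 with slide as a block), among them Sqle (2.59) and the sterol-sensing transcription factor gene Srebf2, whose probes differed by 3.28 and 0.27. For the lysosome, matrix and cholesterol lists an estimated correlation gave adjusted p-values of 0.55, 0.28 and 0.55.

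Of 16 complement genes 9 fell and 2 rose (9 and 4 adjusted over the list alone; 0.016; 9 and 1 with slide as a block), with factor B, Cfb, at -6.05, C4b at -5.94 and the receptor gene C3ar1 at 1.22. Of 23 type I interferon response genes 14 fell and 2 rose (15 and 2 adjusted over the list alone; 0.0042), but 6 fell and 1 rose with slide as a block. Ly6a fell by 3.93 and Oasl1 rose by 2.62. Of 34 cell cycle genes 18 fell and 5 rose on either count (0.033; 9 and 2 with slide as a block), with Ube2c at -1.72. Of 18 glycolysis genes 9 rose and 5 fell (10 and 5 adjusted over the list alone; 0.033; 9 and 1 with slide as a block), with Slc2a1 at 3.74 and the hexokinase gene Hk3 at 2.35. With an estimated correlation the adjusted p-values of these 4 lists were 0.28, 0.64, 0.64 and 0.64. The median of the 23 fatty acid oxidation genes was 0.16, 7 rising and 4 falling (8 and 4 adjusted over the list alone; 0.30). Its leading members were Pparg (4.23), a lipid-sensing nuclear receptor, and the coactivator gene Ppargc1a (4.08, and 0.72 on its other probe), which was well above background on 2 of 3 PBS arrays.

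Chemokine genes went both ways, 6 of 24 rising and 8 falling on either count (0.61). The monocyte chemoattractant gene Ccl7 rose by 4.02 and Ccl4 by 4.37, whereas Ccl24, an eosinophil attractant, fell by 5.82. Of 24 retinoid genes 5 rose and 8 fell on either count (0.26): the retinol dehydrogenase gene Dhrs9 rose by 4.70, the retinoic acid receptor gene Rarb fell by 2.94 and the retinoic acid-degrading enzyme gene Cyp26a1 fell by 4.22. B cell markers were lower in 8 of 13 cases and higher in 1 (8 and 2 adjusted over the list alone; 0.12; 6 and 1 with slide as a block, 0.028), with Bank1 at -3.79 and Ms4a1 at -3.04.

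Between Thio and PBS 9052 genes were called, 4119 higher and 4933 lower, of which 5131 differed at least 2-fold. With slide as a block, where the comparison rests on Thio 1 against the PBS arrays, 6003 genes were called (3071 higher, 2932 lower), and 4631 of these were called in the same direction in both fits. Both fits hold Thio 1 and the PBS arrays, so their shared calls are not independent. With slide as a block Thio 1 adds nothing to the spread, which comes from the other arrays. Without Thio 1 there were 13876 calls, but Thio and PBS then share no slide, so treatment and slide cannot be told apart. In that fit the interferon list had an adjusted p of 0.094, complement, glycolysis and cell cycle 0.20 each, and cholesterol synthesis 0.058. Of 61 genes named for this comparison 60 were called, and 57 of these were called in the same direction with slide as a block. Epx and Flt3 were not (adjusted p of 0.26 and 0.92), and Gpnmb had no value because its spot on Thio 1 was left out. Alox15 was at -5.21 on Thio 1 but at -1.45 and -2.05 on Thio 2 and 3, so that it differed by -12.39 with slide as a block.

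The third comparison asked what IL-4c does to elicited macrophages. Alternative activation genes rose: Arg1 by 3.65 (SE 0.20), Retnla by 4.03 (SE 0.10), Chil3 by 3.17 (SE 0.17) and Mrc1 by 1.54 (SE 0.16), with 4 Thio+IL-4c against 3 Thio arrays. The chemokine gene Ccl24 rose by 8.47 (SE 0.21), from -1.14 ± 0.52 to 7.34 ± 0.10, a 355-fold difference. Pdcd1lg2, a ligand that restrains T cells, rose by 3.31 (SE 0.20) and Aldh1a2 by 4.42 (SE 0.11). Of 27 measured alternative activation genes 22 rose and 3 fell, with a median of 3.31.

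The other large rises were those of Ddx4, known as a germ cell RNA helicase (8.37, SE 0.29), the cholesterol hydroxylase gene Ch25h (8.35, SE 0.45), the tubulin gene Tuba8 (8.28, SE 0.45) and Tarm1, a receptor of myeloid cells (7.52, SE 0.33). Ch25h and Tarm1 were well above background on 1 of 3 Thio arrays, and Tuba8 on 2. The largest falls were those of the prostaglandin D synthase gene Hpgds (-8.90, SE 0.64), the thyroid hormone deiodinase gene Dio2 (-6.61, SE 0.25), Lrrc14b (-6.46, SE 0.44), Mamdc2 (-6.32, SE 0.18) and the apolipoprotein gene Apoe (-5.92, SE 0.16). Hpgds and Lrrc14b were well above background on 1 of 4 Thio+IL-4c arrays. Ccr2 rose by 2.70, Mki67 by 3.08 and Timd4 by 1.1 (adjusted p = 0.041), while Adgre1 fell by 1.20. Timd4 differed by 0.47 (adjusted p = 0.068) with slide as a block. Ucp1 differed by -0.68 (adjusted p = 0.29), Cx3cr1 by -0.09 (0.70, with 1 of 2 probes going the other way), Gata6 by 0.70 (0.15, but 1.08 and 0.028 with slide as a block) and Itgam by 0.09 (0.49, but 0.43 and 0.047 on the mean of its probes).

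The rise of the alternative activation list (camera adjusted p = 2.2e-14; 23 and 3 adjusted over the list alone) stayed past the threshold with an estimated correlation (6e-04). Cdh1 rose by 7.06 in it and F13a1 fell by 1.61. Of 34 cell cycle genes 26 rose (29 adjusted over the list alone) and none fell (6.4e-12), with Rrm2 at 3.46 and the survivin gene Birc5 at 3.15. Of 13 MHC class II genes 10 rose (11 adjusted over the list alone) and none fell (3.3e-05), with H2-DMb2 at 4.06 and H2-Aa at 2.70. Of 26 lysosome genes 21 fell (23 adjusted over the list alone) and none rose (9.8e-09), including Tfeb (-2.42), the transcription factor of lysosomal genes, and Ctsk (-2.17). Of 24 oxidative phosphorylation genes 16 rose (19 adjusted over the list alone) and none fell (9.1e-06), with Cycs at 1.12 and Uqcrc1 at 0.96. For Cycs all 3 probes rose, by 0.46 to 1.12, and their mean missed the threshold (0.83, adjusted p = 0.11). Of 18 glycolysis genes 10 rose and 2 fell on either count (0.0049), led by Pfkp (1.93, and 0.67 on its other probe) and Hk2 (1.88). With an estimated correlation the adjusted p-values of these 5 lists were 0.25, 0.25, 0.44, 0.46 and 0.58 in the same order.

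Of 24 chemokine genes 12 rose and 5 fell (13 and 5 adjusted over the list alone; 0.018), with the T cell attractant gene Ccl17 at 5.04, platelet factor Pf4 at -2.18 and Ccl3 at -2.79. Of 22 scavenger receptor genes 13 fell and 4 rose on either count (0.016), with Colec12 at -4.43, the bridging protein gene Gas6 at -4.09 and the oxidised lipoprotein receptor gene Olr1 at 4.51. Both lists missed the threshold with slide as a block (0.059 and 0.057) and with an estimated correlation (0.46 and 0.42). Of 27 matrix and repair genes 12 fell and 4 rose (12 and 7 adjusted over the list alone; 0.31): the protease inhibitor gene Timp1 rose by 5.55 and osteopontin, Spp1, fell by 4.15. Mesothelial and stromal markers fell in 3 of 12 cases on either count, none rising (0.43). Of 19 resident list genes 6 rose and 6 fell (7 and 6 adjusted over the list alone; 0.84), with the growth factor gene Hgf at -4.10 and the complement receptor gene Vsig4 at -3.58. Of 24 retinoid genes 6 rose and 4 fell on either count (0.33), with the retinol carrier gene Rbp4 at 3.82. Among markers of other cells, B cell markers fell in 5 of 13 cases and rose in 1 (6 and 1 adjusted over the list alone; 0.18) while class II genes rose. Dendritic cell markers rose in 2 of 8 cases and fell in 1 on either count (median 0.89, 0.20, and 0.45 with an estimated correlation). With probes well above background on all 14 arrays their median was 1.33 (0.043).

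Between Thio+IL-4c and Thio 8007 genes were called, 3303 higher and 4704 lower, of which 3980 differed at least 2-fold. With slide as a block 8558 were called, and 7048 were called in the same direction in both fits. Of the calls 41.3% were higher, and 49.3% with slide as a block. Of 15 monocyte genes 6 rose and 1 fell (7 and 1 adjusted over the list alone; 0.016, and 0.25 with an estimated correlation), with Plac8 at 2.16 (0.60 on its other probe).

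The fourth comparison set the IL-4c-treated macrophages of both origins against each other. The levels of Arg1, Retnla and Chil3 differed by -0.10 (SE 0.19, adjusted p = 0.66), 0.12 (SE 0.10, 0.30) and 0.13 (SE 0.16, 0.48) between Thio+IL-4c and IL-4c, with 4 arrays in each group. Groups on different slides were compared here, so a missing call does not show equal levels. Other index genes differed. Mrc1 was higher in Thio+IL-4c by 5.15 (SE 0.15), Pdcd1lg2 by 4.19 (SE 0.19) and Aldh1a2 by 1.83 (SE 0.10), whereas Ucp1 was lower (-9.95, SE 0.46). Arg1, Retnla and Chil3 ranked between 2 and 35 of 55681 probes on the arrays of both groups, where the signal of the brightest spots can be compressed. In the authors' table Arg1 differed by -0.47 (adjusted p = 0.032), which is about the all-gene median of -0.43 there and so gives it no direction of its own.

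The largest rises in elicited over resident cells under IL-4c were those of Gpnmb (9.14, SE 0.59), the integrin gene Itgax (CD11c; 8.71, SE 0.20), Ccl7 (8.65, SE 0.21), Atp6v0d2 (8.39, SE 0.46) and Ctsk (8.24, SE 0.30). After Ucp1, the largest falls were those of Serpinb7 (-9.76, SE 0.55), Prg4 (-9.62, SE 0.20, and -1.27 on its other probe), Ltbp1 (-8.66, SE 0.24) and Tmigd1 (-8.59, SE 0.98). On the Thio+IL-4c arrays Serpinb7 was well above background on 2 of 4, Ltbp1 on 1 and Tmigd1 on 3, and Gpnmb was so on 3 of 4 IL-4c arrays. Ccr2 was higher by 7.64 (SE 0.24) and Cx3cr1 by 0.91 (SE 0.18, and 4.04 on its other probe). Gata6 was lower (-5.30, SE 0.34), as were Timd4 (-4.08), Mki67 (-2.35), Adgre1 (-2.74) and Itgam (-1.55). With slide as a block Itgax differed by 8.92, Ucp1 by -8.76, Mrc1 by 5.41, Pdcd1lg2 by 3.93, Ccr2 by 8.12 and Gata6 by -4.14, and each stayed past the threshold.

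Of 19 resident list genes 18 were lower and none higher (the same adjusted over the list alone; median -4.08, camera adjusted p = 2.3e-07, and 0.018 with an estimated correlation). Of its members 17 were called lower with slide as a block. They included the plasminogen activator inhibitor gene Serpinb2 (-6.90). Of 13 MHC class II genes 11 were higher and none lower on either count (2.1e-05), 9 with slide as a block, with H2-DMb2 at 4.53. Of 24 chemokine genes 15 were higher and 4 lower on either count (3e-05; 14 and 2 with slide as a block), with Ccl3 at 6.84 and Ccl2 at 6.48. The chemokine gene Ccl22, not well above background on any IL-4c array, was at least 16.3-fold higher. Of 23 interferon response genes 20 were lower and none higher on either count (5.4e-05), but 10 with slide as a block, with Ly6a at -4.64 and the guanylate-binding protein gene Gbp3 at -4.29. Of 34 cell cycle genes 31 were lower and 1 higher on either count (2.2e-06; 23 and 1 with slide as a block), with Kif23 at -3.0 and the cyclin gene Ccna2 at -3.12. With an estimated correlation the adjusted p-values of these 4 lists were 0.16, 0.16, 0.44 and 0.29.

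Of 24 oxidative phosphorylation genes 21 were lower (22 adjusted over the list alone) and none higher (0.00019), yet 7 with slide as a block, with Ndufs1 at -1.18 and Cyc1 at -1.07. Of 23 fatty acid oxidation genes 18 were lower and 3 higher (19 and 3 adjusted over the list alone; 0.0033; 12 and 2 with slide as a block), with Hadh at -2.15 and Acaa2 at -1.83 against Pparg at 2.41 and Ppargc1a at 3.51. For Ppargc1a, 1 of 2 probes went the other way and the mean of both missed the threshold (0.47, adjusted p = 0.17). Of 27 matrix and repair genes 16 were higher and 7 lower on either count (0.0015; 12 and 2 with slide as a block), with the collagenase gene Mmp13 at 6.85 and Timp1 at 5.90. Mesothelial and stromal markers were higher in 4 of 12 cases and lower in 3 on either count (0.36; 1 and 2 with slide as a block). Of 27 alternative activation genes 16 were higher and 4 lower on either count (0.00019; 12 and 5 with slide as a block), with Alox15 at -4.07. The median of that list was 1.62, and 0.47 with slide as a block. With an estimated correlation the adjusted p-values of these 4 lists were 0.44, 0.44, 0.16 and 0.049, the last still past the threshold, though 0.11 with slide as a block. Ccl3 and Mmp13 were well above background on 2 of 4 IL-4c arrays.

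Of 24 inflammatory genes 10 were higher and 7 lower on either count (0.054), the acute phase gene Saa3 being lower (-7.36). Of 24 retinoid genes 6 were higher and 11 lower on either count (0.89; 3 and 5 with slide as a block): Rbp4, not well above background on any IL-4c array, was at least 88.4-fold higher, and Cyp26a1 was lower (-3.49). Of 15 monocyte genes 10 were higher and 4 lower on either count (0.0054, and 0.13 with an estimated correlation), 7 and 1 with slide as a block. T and NK cell markers were higher in 6 of 15 cases and lower in 2 (5 and 2 adjusted over the list alone; 0.046, 0.16 with an estimated correlation, 0.51 with slide as a block). Of 12 neutrophil markers 8 were higher and 2 lower (8 and 3 adjusted over the list alone; median 1.82, 0.054, and 0.16 with an estimated correlation), 3 and 1 with slide as a block (0.12). That list passed the threshold in the authors' table (0.029) and on the mean of probes (0.021), and it shares Mmp8 with the matrix list. B cell markers were higher in 5 of 13 cases and lower in 8 on either count (0.66; 1 and 2 with slide as a block), beside the higher class II genes. Dendritic cell markers were higher in 3 of 8 cases and lower in 2 on either count (0.42; 3 and 0 with slide as a block).

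Between Thio+IL-4c and IL-4c 14250 genes were called, 5673 higher and 8577 lower, of which 9445 differed at least 2-fold. These groups shared no slide. With slide as a block, through the Thio arrays on both slides, 5417 genes were called (2468 higher, 2949 lower). Of these, 4110 were called in the same direction in both fits and 156 in opposite directions. The median over all genes was -0.21, and -0.43 in the authors' table, so values near those sizes carry no direction of their own. Of 56 genes named for this comparison 53 were called, of which 50 were called in the same direction with slide as a block. Flt3 and Plac8 were not (adjusted p of 0.19 and 0.47), and Gpnmb had no value there.

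**Figure D3:**
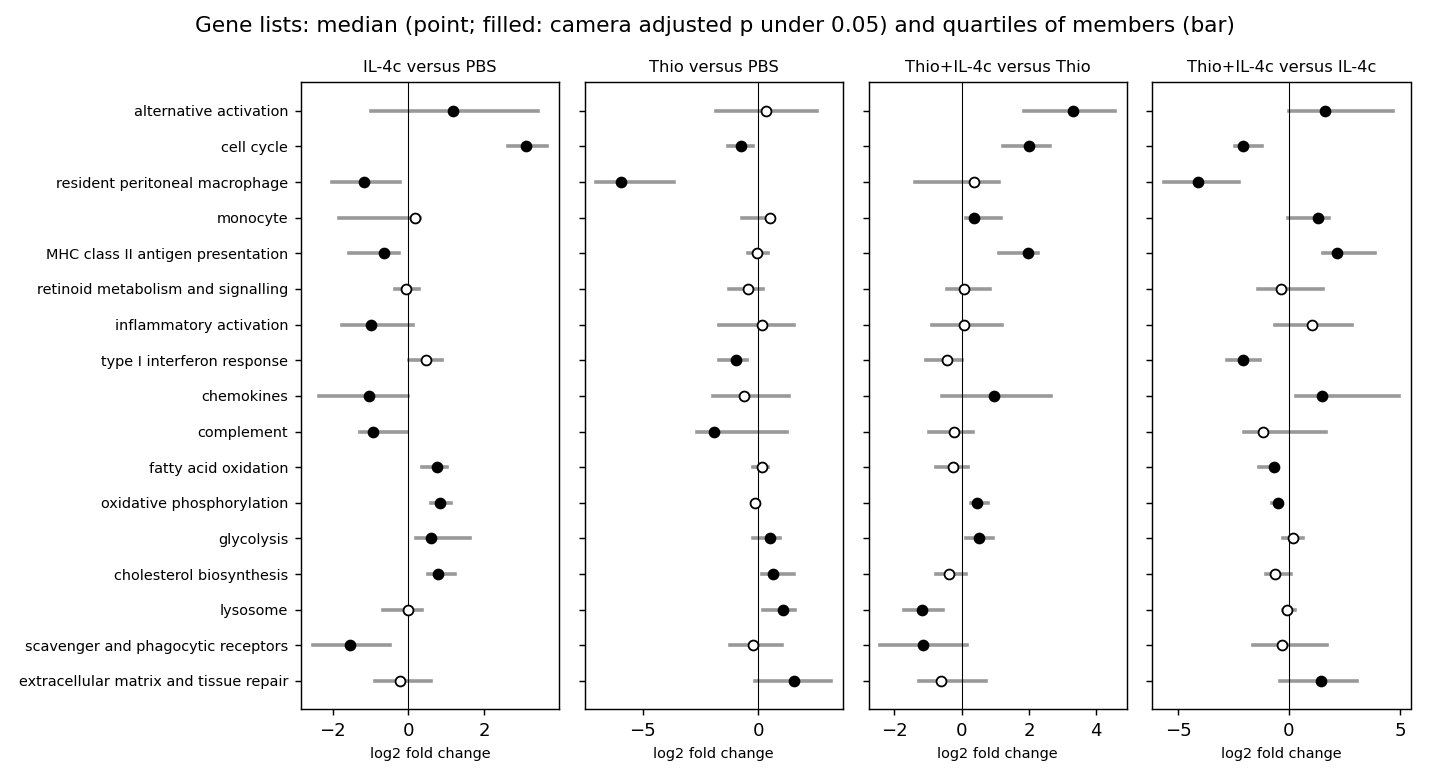
Median log2 fold change (points) and quartiles (bars) of the members of 17 gene lists in 4 comparisons; filled points mark a camera adjusted p under 0.05 at the preset correlation. The cell cycle list lies at 3.11 in IL-4c versus PBS and at -2.05 in Thio+IL-4c versus IL-4c, and the resident list at -5.94 in Thio versus PBS.

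The fifth comparison tested whether the IL-4c response differed between elicited and resident cells. Ccl24 differed most toward elicited cells: it fell by 2.01 with IL-4c in resident cells and rose by 8.47 in elicited cells, an interaction of 10.49 (SE 0.29). Syt10, a synaptotagmin, differed most the other way (-10.94, SE 0.38), rising by 5.76 in resident and falling by 5.19 in elicited cells. Spp1 rose by 4.15 in resident cells and fell by 4.15 in elicited cells (-8.30, SE 0.57). Responses were more positive in elicited cells for Retnla (3.47, SE 0.15), Mrc1 (2.50, SE 0.23), Pdcd1lg2 (2.85, SE 0.29) and Aldh1a2 (3.73, SE 0.16). In resident cells Mrc1 fell and Pdcd1lg2 was not called. Ucp1 and Chil3 responded more positively in resident cells (-6.68, SE 0.71, and -2.86, SE 0.25), and Ucp1 was not called in elicited cells. Retnla and Chil3 ranked between 2 and 27 of 55681 probes in both IL-4c groups, where signals can be compressed. Retnla started lower and Chil3 higher in Thio than in PBS, so their interactions cannot be told apart from these start levels. For Arg1 the difference was -0.41 (SE 0.28, adjusted p = 0.30), and -0.93 (adjusted p = 0.015) in the authors' table, whose all-gene median was -0.20.

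Other large differences toward elicited cells were those of Cxcl13 (8.84), the receptor gene Cd226 (8.62), Hspa1a (8.59) and the phospholipid transfer protein gene Pltp (7.57). Cxcl13 fell by 9.41 in resident cells and differed by -0.57 (adjusted p = 0.17) in elicited cells, where it was already low. Toward resident cells they were those of Cd109 (-8.95), Hpgds (-8.20) and the semaphorin receptor gene Plxna2 (-8.03). The interaction was 6.35 for Ccr2, 2.63 for Timd4 and -0.92 for Adgre1, all past the threshold. It was 0.22 (adjusted p = 0.56; 1.69 on its other probe) for Cx3cr1, 0.64 (0.36) for Gata6, -0.46 (0.32) for Mki67 and 0.26 (0.21) for Itgam. Each of these passed the threshold under some alternative: Cx3cr1 with slide as a block (0.50, 0.038) and on the mean of its probes (0.96, 0.011), Itgam with slide as a block (0.35, 0.049) and array weights (0.32, 0.037), Gata6 with array weights (1.1, 0.028) and Mki67 in the authors' table (-0.98, 0.02).

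By list, 15 of 24 chemokine genes responded more positively in elicited cells and none less so (16 and 0 adjusted over the list alone; median 2.29, camera adjusted p = 1.9e-09, and 0.063 with an estimated correlation). For alternative activation the numbers were 17 and 3 of 27 (17 and 4 adjusted over the list alone; 3.3e-06), the one list that stayed past the threshold with an estimated correlation (0.024, but 0.079 with slide as a block), with F13a1 at 6.17 (3.33 on its other probe). F13a1 fell with IL-4c in both kinds of cell (-7.77 in resident, -1.61 in elicited), so its interaction is a smaller fall. The numbers were 11 and 1 of 13 for MHC class II on either count (6.3e-06), with H2-DMb2 at 6.39 and H2-Oa at 4.67. H2-DMb2 fell by 2.33 in resident cells and rose by 4.06 in elicited cells. In the other direction, cholesterol synthesis genes responded less positively in elicited cells in 17 of 24 cases (18 adjusted over the list alone; 2.7e-06), with Srebf2 at -3.22 (-0.71 on its other probe) and Tm7sf2 at -2.48. So did 15 of 23 fatty acid oxidation genes (17 adjusted over the list alone), 1 going the other way (3.3e-06), with Acadl at -2.58 and Acaa2 at -1.99. The same held for 16 of 26 lysosome genes (17 adjusted over the list alone) against 1 (2.4e-05), with Ctsa at -3.45 (-1.52 on its other probe), and for 12 of 34 cell cycle genes (19 adjusted over the list alone) against none (3.5e-05), with Tpx2 at -3.24 and Ccna2 at -2.86. For Tpx2, 1 of 2 probes went the other way and their mean missed the threshold (-0.85, adjusted p = 0.08). For the last 5 lists an estimated correlation gave adjusted p-values of 0.15, 0.21, 0.21, 0.36 and 0.30. Of 15 monocyte genes 9 responded more positively and 3 less on either count (0.0037, and 0.12 with an estimated correlation), with Hp at 5.74. Of 19 resident genes 8 did so and 4 less (10 and 4 adjusted over the list alone; 0.0032, and 0.14 with an estimated correlation), with Apoc1 at 4.23. In Thio 18 of the 19 were already lower than in PBS (median -5.94), which left less room for a fall. The interaction of this list cannot be told apart from these start levels. Of 24 retinoid genes 5 responded more positively and 2 less on either count (0.075), with Rbp4 at 4.74, though 2 of the 4 groups were not well above background for Rbp4. Of 8 dendritic cell markers 2 did so and none less (4 and 1 adjusted over the list alone; 0.12, and 0.21 with an estimated correlation), beside the class II genes. With probes well above background on all 14 arrays their median was 1.13 (0.021). Inflammatory genes (10 and 2 of 24; 0.00081), immediate early and heat shock genes (6 and 1 of 14; 0.0036), complement genes (6 and 2 of 16; 0.033) and T and NK cell markers (3 and 1 of 15; 0.048) also responded more positively in elicited cells, but the last 2 lists missed the threshold with slide as a block (0.091 and 0.06). Oxidative phosphorylation (0 and 12 of 24; 0.0032) and interferon response genes (0 and 12 of 23; 0.008) responded less so. Adjusted over the list alone these numbers were 11 and 2, 7 and 1, 7 and 2, 3 and 1, 0 and 12, and 1 and 13, and none of these 6 lists passed with an estimated correlation (adjusted p of 0.17, 0.28, 0.17, 0.17, 0.48 and 0.58).

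An interaction was called for 6642 genes, 2588 toward elicited and 4054 toward resident cells. With slide as a block it was called for 8157, of which 3846 went toward elicited and 4311 toward resident cells. The share toward elicited cells was 39% and 47.1% in these fits, so the imbalance was smaller within slides. In both fits 6361 genes were called in the same direction. Across 20343 genes the IL-4c responses of resident and elicited cells, which share no array, correlated at Pearson's r of 0.177 and Spearman's rho of 0.061, with a covariance of 0.192 (r 0.243 with slide as a block). Genes are not independent replicates. In both kinds of cell 1494 genes rose, where independent lists would share 557, and 1457 fell, where they would share 720. Another 661 genes rose in resident and fell in elicited cells (793 for independent lists) and 435 did the reverse (506). Of the genes called with the same sign in both responses (1494 and 1457), 1109 also had an interaction. All genes called with opposite signs had one (1096). Opposite calls all but fix that outcome, so it adds no evidence of a difference.

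**Figure D4:**
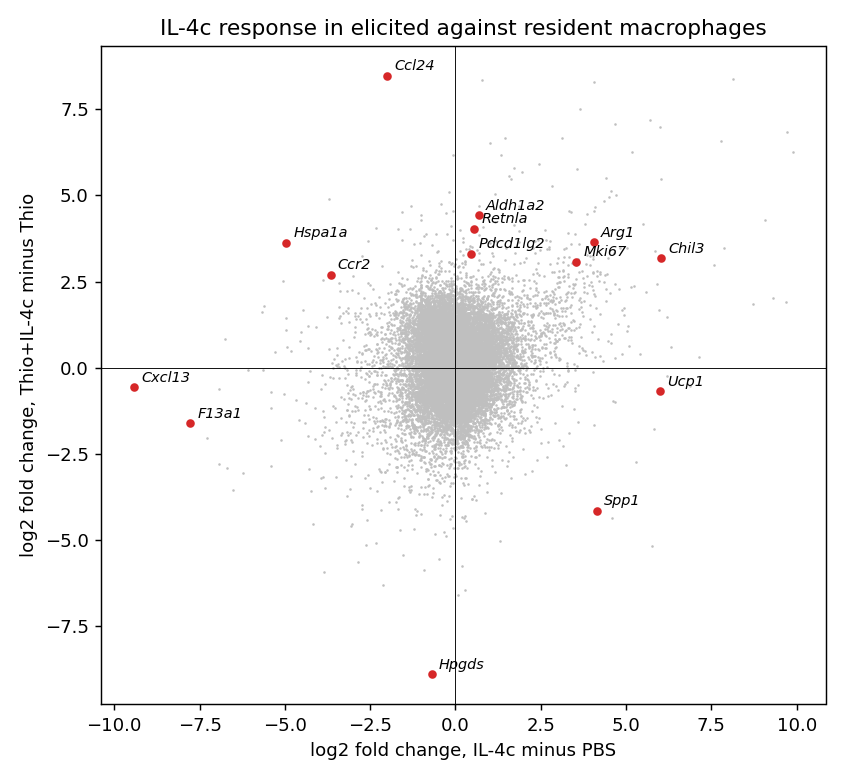
Log2 fold change of each gene with IL-4c in elicited cells (vertical axis, Thio+IL-4c minus Thio) against that in resident cells (horizontal axis, IL-4c minus PBS). Arg1, Chil3 and Mki67 lie high on both axes, Ccl24 and Hspa1a rise only among elicited cells, and Spp1 lies at 4.15 and -4.15.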

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

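Tests of a mixture with resident cells, of a mislabelled Thio 1, of the floor for Ucp1, of the gap between Ucp1 and adipocyte markers, and of a larger macrophage share were chosen after the results were seen. The other tests were written down before they were run. Those on Thio 1, Ucp1 and B cell markers concern patterns of these results.

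The IL-4c response differed between elicited and resident cells, by the interaction test, for 6642 genes. With IL-4c, Retnla and Chil3 were among the brightest probes, where signals can be compressed, so their values cannot be told apart from their start levels. Cxcl13, Timd4 and Apoc1 belong to the resident list, most of which was already lower in Thio than in PBS. Start levels may therefore enter their values too. F13a1 fell with IL-4c in both kinds of cell, less so in elicited cells. Toward elicited cells the differences were 10.49 for Ccl24, 8.84 for Cxcl13, 8.62 for Cd226, 8.59 for Hspa1a, 7.57 for Pltp, 6.39 for H2-DMb2, 6.35 for Ccr2, 6.17 for F13a1, 5.74 for Hp, 4.74 for Rbp4 (2 of its 4 groups not well above background, so this size rests on floor values), 4.67 for H2-Oa, 4.23 for Apoc1, 3.73 for Aldh1a2, 3.47 for Retnla, 2.85 for Pdcd1lg2, 2.63 for Timd4 and 2.50 for Mrc1. Toward resident cells they were -10.94 for Syt10, -8.95 for Cd109, -8.30 for Spp1, -8.20 for Hpgds, -8.03 for Plxna2, -6.68 for Ucp1, -3.45 for Ctsa, -3.24 for Tpx2 (1 of 2 probes opposite, their mean -0.85 with an adjusted p of 0.08), -3.22 for Srebf2 (-0.71 on its other probe), -2.86 for Chil3, -2.86 for Ccna2, -2.58 for Acadl, -2.48 for Tm7sf2, -1.99 for Acaa2 and -0.92 for Adgre1.

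In 18 of 292 combinations of a named gene and a group of 4 arrays, 1 array lay far from the other arrays. Chance marks about 1 in 20 such groups. Among IL-4c arrays these were Retnlg on IL-4c 1 (1.86, the others -2.28 to -1.79), Gpnmb on IL-4c 1 (-6.52), Ccr2 on IL-4c 1 (-4.40), Timd2 on IL-4c 1 (3.74), Ms4a1 on IL-4c 2 (-3.13), C4b on IL-4c 3 (6.49), Hspa1a on IL-4c 3 (-2.26), Ube2c on IL-4c 3 (4.09), Ltbp1 on IL-4c 4 (2.42) and Wt1 on IL-4c 4 (-8.29). Among Thio+IL-4c arrays they were Timd2 (-3.43) and Kif23 (-1.26) on array 1, Lrrc14b on array 2 (-8.52), and Atp6v0d2 (2.55), Batf3 (3.92), Hgf (-5.05), Ppargc1b (-1.26) and Serpinb2 (1.15, the others -2.01 to -1.49) on array 4. Probes without a gene symbol, which no comparison used, were also called: 2942 for IL-4c versus PBS, 7126 for Thio versus PBS, 4399 for Thio+IL-4c versus Thio, 18680 for Thio+IL-4c versus IL-4c and 3868 for the interaction. These numbers were 6604, 2996, 6095, 3148 and 6902 in the same order with slide as a block.

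Other splits of the same arrays into groups of these sizes were fitted for each comparison. For IL-4c versus PBS 1 of 35 splits, the real one, gave 6546 genes and the highest other 49. The same held for Thio+IL-4c versus Thio (8007 against 3223, 1 of 35) and Thio+IL-4c versus IL-4c (14250 against 2, 1 of 35). This argues against a chance division if the arrays are exchangeable, which the labels do not settle. Real differences also enter the spread of the other splits and lower their numbers. For the interaction 1 of 100 splits, the real one, gave 6642 genes against 2244. That shuffle also removed the IL-4c effects themselves, so it cannot decide whether they differ. For Thio+IL-4c versus IL-4c the real split is also the split by slide, so its count does not set the treatment apart from slide. With slide as a block 5417 genes were called, 156 of them in the opposite direction. For Thio versus PBS the 10 splits are too few for a share under 0.05, with 9052 genes in the real split, the 1 as large, and 3780 in the highest other.

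Thio 1, the only Thio array on slide 1, stands apart from Thio 2 and 3, with 8725 genes more than 2-fold apart. A slide batch acting probe by probe would give a low correlation between probes of a gene, which is what the test found. Across 3839 genes with 2 probes, the difference of Thio 2 and 3 from Thio 1 correlated between probes at r of 0.05. That of IL-4c 1 and 2 from PBS 1 correlated at 0.55, but those arrays also differ by treatment. Another technical difference of Thio 1 could give as low an r, so the test does not single out slide. Resident macrophages mixed into Thio 1 are argued against by 12 resident list members, whose median level there was 0.55% of PBS. A mislabelled PBS or IL-4c array was first looked for as the share of genes 16-fold apart in which Thio 1 lies nearer to PBS, which was 78.8%, but the shared slide fixes that outcome, so it decides nothing. Within slide 1, Thio 1 lay below every PBS and IL-4c array in 18 of 18 resident list members that are lower in Thio 2 and 3, which argues against mislabelling.

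Ucp1, seen by 1 probe, was higher in IL-4c than in PBS, and the lower floor of the brighter IL-4c arrays is argued against by a log2 gap of 5.05 between the lowest IL-4c and the highest PBS array. For adipocytes, which the CD11b and F4/80 gate should remove, the test set beforehand was undecided: the median of 12 markers was 0.40, with 3 higher (Plin1 3.58, Cox7a1 1.91, Retn 1.39), exactly at its bound. The 10 markers no brighter than Ucp1 in PBS had a median 5.09 below its rise of 6.00, but picking them compares levels of different probes, so it decides nothing and adipocytes stay open. Cidea (0.10), Cox8b (0.02) and Adipoq (0.70) were not called, nor was Elovl3 (1.40), and Fabp4 fell by 0.64. A response of the macrophages to IL-4c stays open as an untested explanation.

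B cell markers were lower in IL-4c than in PBS. The lower floor of the brighter IL-4c arrays is argued against, since 0 of 10000 random lists matched on PBS level had a median as low as -1.20 (median of the random lists -0.03). A larger share of macrophages in the IL-4c sort would lower markers of all other cells alike, and the medians of 5 such lists lay 1.55 apart against a mean interquartile range of 1.40. That gap stayed the larger without the T and NK list (1.55 against 1.43) and without the mast cell list (1.55 against 1.25). It rests on single lists, though, being 0.78 (1.36) without the dendritic list of 6 members and 1.0 (1.36) without the B cell list. Without the neutrophil list it was 1.55 (1.62), so this explanation stays open. Fewer B cells in the IL-4c sort may account for the decline, as may lower expression of these genes in the sorted cells, and neither was tested.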

How the results depend on the processing

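Slide as a random block and leaving out genes below background in both groups were chosen after the data were seen. The number of genes called for Thio versus PBS was 3919 with only the groups compared, 14512 with array weights, 6003 with slide as a block, 5844 with slide as a random block and 5331 at an adjusted p under 0.01. For Thio+IL-4c versus IL-4c it was 5417 with slide as a block and 5595 with slide as a random block, and for the interaction 4327 at an adjusted p under 0.01, where the stricter threshold is the cause. The share of variance of thioglycollate fell to 7.40% with slide as a block, since slide was entered first. For the other changes the cause was not tested. Leaving out 1 array gave 5535 to 8792 genes for IL-4c versus PBS, 6231 to 13876 for Thio versus PBS (the highest without Thio 1), 6943 to 8991 for Thio+IL-4c versus Thio, 13314 to 15390 for Thio+IL-4c versus IL-4c and 5728 to 8154 for the interaction. The correlation of the responses ran from 0.128 to 0.243 and the share of thioglycollate from 49.7% to 64.8%, the highest of both without Thio 1. Thioglycollate and slide coincide without Thio 1, so the calls for Thio versus PBS and that share then cannot be told apart from slide.

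Directions turned for Adgre1 in IL-4c versus PBS (-0.27), which was 0.01 with quantile normalization, 0.03 with normexp and quantile normalization and 0.09 in the authors' table, and in Thio versus PBS for Epx (-0.14 in the authors' table) and Flt3 (-0.09 with slide as a block). Over all alternatives, 7057 gene results kept their side of the threshold without a reversal, 77 lost the call, 21 gained one and 5 reversed. Of list results 3386 did so, 68 lost the call and 30 gained one. A change of sign where neither fit called the gene or list was counted as kept. A kept direction is therefore known only for called results. Among results on whole comparisons 180 stayed the same and 11 moved. Scan date equals slide and was not run apart. Trend and robust priors gave no value for the response correlation and the variance, array weights and the random block none for the variance, and only the groups compared none for the interaction, the correlation and the variance. Genes near background are the limit of the signal.

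Replicate numbers do not pair the arrays: 4 of 19 same-numbered pairs correlated above 0.1 (range -0.45 to 0.37) and 2 of 14 arrays matched best with their own number. With the replicate number as a block there were 5792, 7744, 6975, 13727 and 5840 genes in the order of the comparisons, a response correlation of 0.192 and a share of 51.5%.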

Other observations

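Genes of the other lists, taken by the same rule, also differed. Cebpe, a granulocyte transcription factor, rose with IL-4c by 4.05 in resident and 4.56 in elicited cells. Retnlg, of the neutrophil list, rose by 3.40 and 4.51, the first with IL-4c 1 alone at 1.86. In resident cells S100a8 fell by 3.07 and the mast cell genes Cma1 and Cpa3 by 2.54 and 2.49, while the interferon response genes Oasl1 and Ly6a rose by 4.23 and 2.28. In elicited cells S100a9 rose by 2.82, while Rsad2 fell by 2.31, Ifit3 by 2.15 and Il7r by 3.34. Of the dendritic cell list, Batf3 rose by 1.0 in resident and 2.71 in elicited cells, and Cd209a by 1.17 (adjusted p = 0.042) and 2.62. The first call was lost with quantile normalization (0.088), normexp with quantile normalization (0.072) and the mean of its probes (0.073). It was also lost without PBS 1 (0.90, 0.17), PBS 3, any 1 IL-4c array, Thio 2, Thio 3 or Thio+IL-4c 1 (adjusted p of 0.053 to 0.091 for these). Siglecf rose by 0.77 in resident cells and fell by 0.53 (adjusted p = 0.042) in elicited cells, where 1 of 2 probes went the other way. The rise was 0.26 (0.22) in the authors' table. The decline missed the threshold on the mean of its probes (-0.18, 0.56), with the replicate number as a block (0.097), trended and robust priors (0.09), only the groups compared (0.10) and array weights (0.05). Without PBS 2, IL-4c 2 or 3, Thio 2 or 3, or Thio+IL-4c 1, 3 or 4 its adjusted p was 0.051 to 0.12. Hspa1a rose by 3.63 in elicited cells. Wt1, of the mesothelial list, was at least 15.4-fold lower in Thio+IL-4c than in Thio.

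Between Thio and PBS, Siglecf rose by 3.63, S100a6 by 2.24 and Atf3 by 3.29, and Wt1 was at least 7.27-fold higher. Hdc fell by 5.92, Padi4 by 4.48, Cd209a by 3.80, Hp by 4.03 and Hspa1a by 4.22. Of 14 immediate early and heat shock genes 9 fell and 4 rose on either count (median -1.39, camera adjusted p = 0.16, and 0.64 with an estimated correlation). With slide as a block 7 fell and 3 rose. Of 10 mast cell markers 6 fell and none rose on either count (camera adjusted p = 0.12, and 0.55 with an estimated correlation), and 3 fell with slide as a block. Epx was at least 2.41-fold higher (adjusted p = 0.034) but -0.14 in the authors' table, and Flt3 rose by 1.99 but was at -0.09 with slide as a block, with 1 of 2 probes going the other way. Between Thio+IL-4c and IL-4c, S100a9 was higher by 5.65, Il7r by 5.83, Flt3 by 4.29 (1.16 with slide as a block, not called; 1 of 2 probes opposite), Hspa1a by 4.37, Plac8 by 3.39 (0.27 on its other probe; 0.70 with slide as a block, not called), Batf3 by 2.43, Siglecf by 2.33, Hk2 by 1.89 and Pfkp by 1.68, the last with 1 of 2 probes going the other way. Mmp8 was at least 14.4-fold higher, while Hdc (-4.76) and Padi4 (-5.68) were lower. Erythroid and platelet markers were higher in 4 of 7 cases and lower in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.047, 0.29 with an estimated correlation, 0.54 with slide as a block).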
